A study of Mus musculus with 4 samples.

How the data were processed

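Fresh mouse tumour tissue, labelled MB by the submitters, was dissociated and captured on a 10x Genomics Chromium system with the 3' kit of version V3, and the libraries were read on DNBseq instruments. There were 4 libraries, 1 from each combination of genotype and sex. SG stands for the genotype with SMO-M2, a constitutively active form of Smoothened, and hGFAPcre, a Cre recombinase driven by the human GFAP promoter. YSG stands for the same genotype with floxed Yap1 added, described as rescued animals at end point. The number of animals behind each library, their ages, the zygosity of the floxed allele and the exons it removes are not given in the sources used here.

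Per the file headers, Cell Ranger 5.0.1 made the matrices, and the submitters' processing notes name the mm10 build. The values deposited are counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, not normalized, over 32286 features that include an added EYFP sequence. A UMI count sees only the 3' end of a transcript, so it does not show which exons a transcript holds. Gene positions were taken from GENCODE M21, an annotation of mm10. The deposited matrices held 8505 barcodes for SG males, 8013 for YSG males, 7726 for SG females and 7289 for YSG females, and no barcode had fewer than 500 UMIs.

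Cells were kept at 500 or more UMIs, 300 or more genes and at most 20% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 6%. Scrublet's own threshold marked 0% of the cells in each library, so the planned fallback applied: cells with scores above the top 6% mark were removed, which, because scores were tied at the mark, took 4.85%, 5.30%, 4.94% and 5.12% of the SG male, YSG male, SG female and YSG female cells. This left 8011, 7464, 7278 and 6825 cells. Real doublets may remain among them, and some of the cells removed may have been single.

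The 4 libraries were clustered together with no batch correction, because library and group are the same thing here and a correction would remove the comparison. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were reduced to 30 principal components with numpy 2.4.6. Sex-linked genes, Yap1, EYFP, haemoglobin and mitochondrial genes were left out of the variable genes. A graph of 15 nearest neighbours with shared-neighbour weights (scikit-learn 1.9.0) was partitioned with leidenalg 0.10.2 at resolution 1.0, which gave 25 clusters. Clusters were named from marker sets fixed before the data were examined, and a class name means X-like. A class outside the granule lineage needed a mean marker log2 fold of 2 or more and at least 3 markers found in over 10% of the cluster's cells. Of the other clusters, those with at least 3 granule markers were called granule progenitor or differentiating granule neuron by whichever marker set was higher. The scoring rule, unlike the markers, was set after the clusters were seen. Of the 25 clusters, 2 stayed unnamed because their cells' median UMI count was under 1/3 of that of their own libraries and no marker of the granule class they scored for was among their leading genes. Ttr, a choroid plexus marker, led 1 of the 2. No deposited annotation of cells was used.

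With 1 library per group there is no replicate, and cells are not replicates, so no test was made and no p-value is given. Shares of cells carry exact Clopper-Pearson binomial intervals. UMIs were summed per library over the cells of a class, divided by all UMIs of that class on the usual CPM scale and compared as a log2 ratio with a pseudocount of 1 CPM, which understates the ratio of scarce transcripts. Folds come from the counts without a pseudocount, with exact conditional binomial intervals. All intervals are 95% intervals and cover counting error only, not differences between animals, tissue pieces or capture runs. Intervals from summed UMIs treat each UMI as independent, so they also leave out the clumping of UMIs in few cells. Where 1 side had 0 counts, the fold is a lower bound against 3 counts in that library. Computation used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

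Gene lists were fixed before the data were examined. They cover SHH pathway targets, proliferation, granule neuron differentiation, neural stem and glial progenitor genes, YAP and TAZ targets, MHC class I and class II presentation, interferon response, chemokines and cytokines, immune checkpoint ligands, homeostatic and disease-associated microglia, complement and phagocytosis, alternative macrophage activation, T and NK cytotoxicity, T cell exhaustion and regulation, p53 and apoptosis, cholesterol synthesis, hypoxia and glycolysis, extracellular matrix, immediate early and dissociation stress genes, haemoglobin, Y-linked, X inactivation and X-inactivation escape genes. A list's value is the median log2 ratio over members at 5 CPM or more in at least 1 library, where at least 5 members were measured. It is given with an interval from 2000 Poisson resamplings of the counts and with its percentile among 10000 random lists of the same size matched on expression in 20 bins. Members beyond 0.5 on the log2 scale are counted as a description of size. Genes of a list are not independent of each other, so the percentile is not a test between genotypes or sexes.

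Named genes follow a rule fixed before the data were examined. Candidates had 20 CPM or more in at least 1 library, and left out sex-linked lists, haemoglobin, mitochondrial and ribosomal protein genes and names starting with Gm or ending in Rik. For genotype, genes with counting intervals on the same side of 1 in both sexes were ranked by the smaller absolute log2 ratio, and the 10 highest and 10 lowest were named. For sex, the same ranking over the genotypes gave 5 and 5. For genotype ratios that go opposite ways in males and females, the 5 largest and 5 smallest differences were named. Yap1, Wwtr1, Smo, Xist and the Y-linked genes were added, with up to 6 members of each list described. Some of the genes so chosen are not reported here. The rule also left out genes under 1/20 of their level in another class of 50 or more cells in all 4 libraries, and this removed nothing, because 0 other named classes had that many cells in every library. With the libraries pooled, some reported genes lay under that bound. Mxd1 was at 0.0168 of its level in neutrophil-like cells, Igfbp2 at 0.0328 of that in astroglia-like cells and Fosb at 0.0377 of that in endothelial-like cells.

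The intervals and percentiles were tested on simulated data drawn from the pooled sums of the granule lineage. Counts were drawn as independent Poisson values for each gene. This checks the calculation, and does not cover UMIs clumped in few cells or genes that vary together. In the male and female genotype comparisons, 95.4% and 94.9% of the intervals of unchanged genes held the true value, and 100 of 100 genes set at a 2-fold change were recovered in each. Of 200 unchanged lists, 3.5% and 4.5% fell outside the central 95% of random lists.

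Alternatives listed before the data were examined were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), no doublet removal, resolutions of 0.5 and 2.0, each library clustered alone, immune classes called per cell from at least 3 marker UMIs, TMM factors (edgeR 4.0.16 in R 4.3.3), size factors (DESeq2 1.42.0), a pseudocount of 10 CPM, list minimums of 20 CPM and of none, equal weight for each cell, cells thinned to 2000 UMIs, progenitor and differentiating clusters apart, and totals without mitochondrial, ribosomal protein and haemoglobin genes. edgeR and DESeq2 were used for these factors alone. Chosen after seeing the data were leukocytes counted from 2 or more UMIs of Ptprc, Tyrobp, Fcer1g and Laptm5 together, the granule cluster nearest the boundary between the granule classes moved to the other side, and granule-lineage sums without clusters of which 1 library held over 80% of the cells or without clusters led by Hspa1a or Fos. Expression in myeloid cells and in T and NK cells was planned only for 50 or more cells per library and was not compared, because no library had that many.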

Results

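Single-cell transcriptomes of mouse tumours driven by SMO-M2 were compared with and without floxed Yap1, in males and in females. Yap1 encodes a transcriptional coactivator of the Hippo pathway. The title of the series puts the question as one of sex differences in the function of Yap1 in immune evasion. Each of the 4 groups (SG males, YSG males, SG females and YSG females) was 1 library, so the values below have no replicate error and no difference was tested. Genotype and sex cannot be separated from the animal, its age, the litter or the capture run. The deposited matrices held 73271922 UMIs for SG males, 61072375 for YSG males, 86906706 for SG females and 58478914 for YSG females. After filtering, 8011, 7464, 7278 and 6825 cells remained in the same order, with medians of 6018, 5708, 7181 and 6502 UMIs per cell.

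Yap1 transcripts were scarce in both YSG libraries. Over all kept cells there were 232 Yap1 UMIs in SG males and 9 in YSG males, which was 21.5-fold lower in YSG (counting interval 11.1 to 47.5). In females there were 336 and 3, which was 76.3-fold lower (25.9 to 372). Yap1 lies on chromosome 9 at 7931999 to 8004596 of mm10, on the minus strand. The low counts go with the genotype labels, but 3' tags need not lie in the floxed exons, so they do not measure the deletion itself. Wwtr1, which encodes TAZ, the paralog of YAP1, was also lower in YSG, 2.83-fold (2.52 to 3.19) in males and 2.87-fold (2.60 to 3.17) in females over all kept cells. In astroglia-like cells its YSG over SG fold was 0.769 (0.399 to 1.40) in males, and in females, where YSG had only 32 such cells, 3.90 (2.53 to 5.99) on 42 and 51 UMIs. Smo, counted together with any transcript of the SMO-M2 transgene that carries its 3' end, was at 52.4, 57.8, 55.9 and 52.4 CPM in SG males, YSG males, SG females and YSG females. The sex labels were checked with Xist, the RNA that silences 1 X chromosome in females, and with Y-linked genes. Xist was at 0.817 and 0.222 CPM in the male SG and YSG libraries and at 2087 and 1977 CPM in the female ones. Ddx3y was at 195 and 177 CPM in males with 0 UMIs in either female library, which allows up to 3 UMIs in each. Eif2s3y had 0 UMIs in females as well, Uty had 1 and 2, and Kdm5d had 7 and 4.

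Leukocytes made up a larger share of the YSG libraries than of the SG libraries in both sexes. They were 16 of 8011 cells in SG males (0.200%, 0.114 to 0.324%) and 29 of 7464 in YSG males (0.389%, 0.260 to 0.558%), a fold of 1.95 (1.02 to 3.83), whose interval reached below 1 with the stricter filter (0.990 to 5.77) and at resolution 2.0 (0.973 to 3.55). In females they were 9 of 7278 cells (0.124%, 0.0566 to 0.235%) and 45 of 6825 (0.659%, 0.481 to 0.881%), a fold of 5.33 (2.57 to 12.4). The male over female fold was 1.62 (0.672 to 4.15) in SG and 0.589 (0.356 to 0.961) in YSG. These cells formed a microglia-like cluster, led by the lysozyme gene Lyz2, the complement genes C1qa, C1qb and C1qc, the chemokine gene Ccl5 and Cd74, and a neutrophil-like cluster led by S100a8 and S100a9. The microglia-like cluster held 16, 24, 9 and 29 cells in SG males, YSG males, SG females and YSG females. It is a mixture, since single cells in these clusters carried monocyte, dendritic cell or T cell markers. At resolution 2.0 it split into 15, 10, 9 and 18 microglia-like and 2, 14, 0 and 11 dendritic-like cells, so the male microglia-like share was then lower in YSG, with a log2 ratio of −0.48 (−1.80 to 0.77). The neutrophil-like cluster held 5 cells in YSG males and 16 in YSG females. There were 0 such cells in either SG library, with intervals that reached up to 0.046% in males and 0.0507% in females. The neutrophil-like cells were shallow, with a median UMI count of 0.169 of that of their own libraries, so the minimum of 500 UMIs can set their share. Cells of the leukocyte clusters with 2 or more T cell marker UMIs numbered 1, 3, 1 and 3.

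The direction of the leukocyte shares turned under 1 way of counting, in which most calls were granule-lineage cells with Vcan UMIs. When cells were called per cell from at least 3 UMIs of an immune marker set, the YSG over SG log2 ratio was −0.85 in males and −0.23 in females. That rule called 305, 158, 331 and 265 cells in SG males, YSG males, SG females and YSG females, of which 8, 22, 8 and 34 lay in the leukocyte clusters. Its monocyte set holds Vcan, and 246, 96, 269 and 190 granule-lineage cells had 3 or more Vcan UMIs. The rule calls each of these by construction, so most of its calls in every library were such cells. Its ratios are thus not read as a direction of leukocyte shares. With 2 or more UMIs of the pan-leukocyte genes Ptprc, Tyrobp, Fcer1g and Laptm5 together, 15, 26, 11 and 42 cells were counted.

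**Figure D1:**
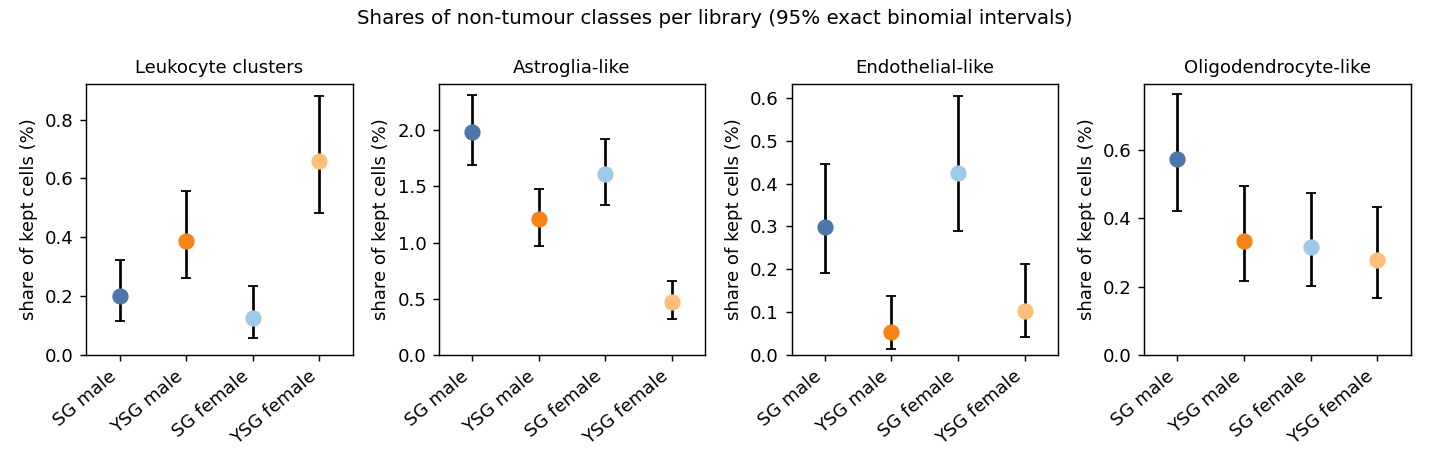
Each panel plots 1 class as its share of kept cells in percent (y axis) for the 4 libraries (x axis), with points for shares and bars for 95% exact binomial intervals, which cover counting error only. Leukocyte clusters range from 0.124% in SG females to 0.659% in YSG females, while astroglia-like cells range from 1.98% in SG males to 0.469% in YSG females.

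With the libraries clustered together, astroglia-like and endothelial-like cells made up smaller shares of the YSG libraries, by an amount that depended on the setting. Astroglia-like cells, led by Aqp4, Fabp7 and Apoe, numbered 159, 90, 117 and 32 in SG males, YSG males, SG females and YSG females. The YSG over SG fold of their share was 0.608 (0.464 to 0.792) in males and 0.292 (0.191 to 0.434) in females. The endothelial-like cluster, led by Cldn5 and Flt1 and holding cells with the fibroblast gene Dcn, numbered 24, 4, 31 and 7 cells. Its fold was 0.179 (0.0451 to 0.521) in males and 0.241 (0.0895 to 0.557) in females. With the stricter filter the astroglia-like fold was 0.384 in males and 0.0878 in females, on 7 and 87 cells in YSG and SG females, at resolution 2.0 it was 0.322 in males, and with each library clustered alone it was 0.594 in females. In males it was 0.830 (0.663 to 1.04) with doublets kept and 0.980 (0.754 to 1.27) with each library clustered alone, and at resolution 2.0 the endothelial-like cluster split into 15, 0, 10 and 0 fibroblast-like and 9, 4, 21 and 7 endothelial-like cells, with endothelial-like folds of 0.477 (0.107 to 1.71) in males and 0.356 (0.128 to 0.868) in females. With each library clustered alone, an endothelial-like cluster was named only in YSG males (31 cells) and SG females (28 cells). Oligodendrocyte-like cells (46, 25, 23 and 19) and oligodendrocyte precursor-like cells (22, 20, 30 and 22) had folds of 0.583 (0.343 to 0.969) and 0.976 (0.505 to 1.87) in males, and of 0.881 (0.454 to 1.69) and 0.782 (0.430 to 1.40) in females. Unnamed cells of low UMI count made up 2.27%, 3.24%, 2.72% and 5.23%.

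Cells of the cerebellar granule lineage, with markers such as Atoh1, Gli1 and Neurod1, made up 94.4%, 94.5%, 94.4% and 92.9% of the cells. The libraries of the genotypes fell largely into different clusters of this lineage. Most SG cells lay in clusters 2, 3, 4, 6 and 9, and most YSG cells in clusters 0, 1, 5 and 7, and values within the lineage compare these clusters too. Clusters called granule progenitor held 71.8%, 46.5%, 75.1% and 30.3% of granule-lineage cells in SG males, YSG males, SG females and YSG females. In males no direction is read from these shares, because cluster 1 lies next to the boundary. It holds 26.9% of the granule-lineage cells in YSG males and 19.4% in YSG females. With it counted as progenitor the shares were 73.7%, 73.3%, 76.0% and 49.7%. In females the share was thus lower in YSG with cluster 1 on either side. Under the other filter and clustering settings the female difference, YSG minus SG, ran from −30.4 to −12.8 percentage points. Its size depended on the setting, and with 1 library per group it was not tested. The share of granule-lineage cells with a UMI of the cell cycle genes Mki67 or Top2a, after thinning each cell to 2000 UMIs, was 39.8%, 35.7%, 43.1% and 29.4%. Shallower cells, 251, 280, 224 and 239 in number, were left out. Without thinning the shares were 52.1%, 49.9%, 56.1% and 41.6%. The same thinned share was 26.3% (17.8 to 36.4%) in oligodendrocyte-like cells, which should not cycle, 29.1% (17.6 to 42.9%) in endothelial-like cells and 23.4% (12.3 to 38.0%) in microglia-like cells. The shares of both YSG libraries lay within all 3 intervals and that of SG males within the endothelial-like one, so none of these shares is read as a share of cycling cells. The median UMI count was 8015 in those oligodendrocyte-like cells and 6738 in the granule-lineage cells of YSG females.

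Within the granule lineage, single genes such as Mndal and Pdlim3 were nearly absent from 1 genotype, and extracellular matrix and stem and glial progenitor genes were lower and granule neuron differentiation genes higher in YSG, in both sexes. Across 10389 genes, the YSG over SG log2 ratios of males and females had a Pearson r of 0.74 and a Spearman rho of 0.65, where genes are not independent replicates. The Y-linked and X inactivation genes were left out. Of 302 genes beyond 2-fold in both sexes, 291 went the same way, 127 higher and 164 lower in YSG.

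The genes named as higher in YSG in both sexes were Mndal, Otx1, Caln1, Myt1l, Camk4, Cacna1e, Galr1, Kcnj6, Rem2 and Syndig1l. Mndal, an interferon-inducible gene of the p200 family, stood apart, with 7 UMIs in SG males and 2510 in YSG males, 427-fold higher (207 to 1063), and with 2 and 4695 in females, 3433-fold higher (950 to 28357). It lies on chromosome 1 at 173849126 to 173942491, on the minus strand. Otx1, a homeobox gene, had log2 ratios of 2.37 in males and 2.73 in females. Myt1l, a neuronal transcription factor, had 2.19 and 2.88. The calcium channel gene Cacna1e had 2.03 and 2.97, the potassium channel gene Kcnj6 had 1.91 and 2.27, and the calcium-dependent kinase gene Camk4 had 2.19 and 2.30. Caln1, which encodes a calcium-binding protein, had 2.73 and 2.35, and the galanin receptor gene Galr1 had 2.01 and 2.64. The remaining pair, Rem2 and Syndig1l, had 1.67 and 1.70 in males and 1.68 and 1.62 in females. Otx1, Caln1 and Galr1 are among the leading genes of clusters 0 and 1, where most cells are YSG.

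Genes named as lower in YSG in both sexes included Pdlim3, Igf2bp1, Cavin1, Hmga2, Des, Col5a2, Grb10, Sema3c and Runx1. Pdlim3, which encodes an actin-associated protein of muscle, was 81.0-fold lower in males (110 against 1.36 CPM) and 87.3-fold lower in females (129 against 1.48 CPM). It lies on chromosome 8 at 45885461 to 45919548, on the plus strand. Igf2bp1 and Hmga2, expressed mainly in fetal tissue, were 62.4-fold and 14.9-fold lower in males and 27.6-fold and 16.5-fold lower in females. Cavin1, a component of caveolae, had log2 ratios of −3.07 in males and −3.08 in females. Des, the gene of the intermediate filament desmin, had −2.77 and −3.05, and the collagen gene Col5a2 had −2.74 and −3.10. Grb10, an imprinted gene, had −2.68 and −3.69, Sema3c had −2.68 and −2.70, and the transcription factor gene Runx1 had −2.69 and −2.66. Runx1 was at 22.2 and 37.1 CPM in the granule lineage of SG males and females. Pdlim3, Hmga2, Cavin1, Col5a2, Sema3c and Runx1 are among the leading genes of SG clusters 2, 3 and 6.

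**Figure D2:**
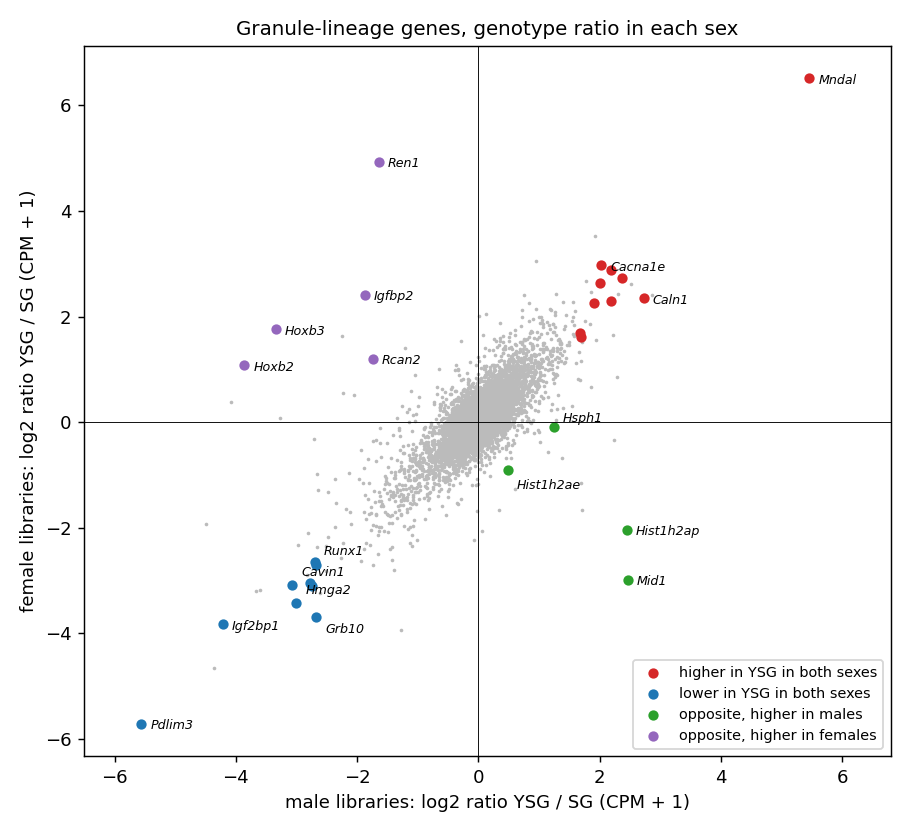
Each grey point is a gene of the granule lineage, at its YSG over SG log2 ratio of CPM plus 1 in males (x axis) and in females (y axis). Coloured points are the genes named by the rule that are reported here. Mndal lies at the upper right at 5.46 and 6.51, Pdlim3 at the lower left at −5.56 and −5.71, and Ren1 at the upper left at −1.64 and 4.93.

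Among the gene lists, extracellular matrix genes and neural stem and glial progenitor genes were lower in YSG and granule neuron differentiation genes were higher, in both sexes. Of 15 measured matrix genes, 11 in males and 10 in females were below −0.5 on the log2 scale, with medians of −1.10 (−1.14 to −0.93) and −1.07 (−1.22 to −0.99), each at percentile 0.00 of matched random lists. The basement membrane genes Col4a1 and Col4a2 had −1.10 and −1.22 in males, Sparc had −1.39, and Lamc1 had −0.20. Endothelial-like cells, which express such genes, made up smaller shares of the YSG libraries too when the libraries were clustered together. Stem and glial progenitor genes had medians of −0.56 (−0.69 to −0.42) and −0.99 (−1.10 to −0.85), with 8 and 10 of 15 below −0.5. Fabp7 had −1.56 and Vim −0.85 in males, while Nes had 0.13 in males and −0.80 in females. Astroglia-like cells, which express Fabp7 and Vim, also made up smaller shares of the YSG libraries when these were clustered together. Fabp7 was at 71.5 and 23.7 CPM in the granule lineage of SG and YSG males, against 3404 and 1801 CPM in astroglia-like cells. RNA from those cells cannot be excluded as its source. Differentiation genes had medians of 0.41 (0.37 to 0.42) in males and 0.69 (0.62 to 0.85) in females, at percentile 100 in both, with 8 and 19 of 23 above 0.5. Stmn2 had 0.81, Zic1 0.53 and Nfix −0.20 in males. Within the differentiating clusters alone the medians were −0.37 and −0.13 for differentiation genes and 0.17 and 0.17 for stem and glial progenitor genes, and that of matrix genes in females was 0.028, so these directions depend on which clusters are compared.

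Proliferation genes had medians of −0.16 (−0.19 to −0.14) in males and −0.43 (−0.45 to −0.40) in females, with 1 and 12 of 30 below −0.5. Top2a had −0.38, Mki67 −0.29 and Aurkb −0.60 in males. This direction also turned within each of the 2 granule classes, with 0.25 and 0.49 in the progenitor clusters and 0.46 and 0.13 in the differentiating clusters. Each class pools different clusters in the 2 genotypes: the differentiating one held 1894 cells of cluster 1, next to the boundary, in YSG males and 1285 cells of cluster 4 in SG males. SHH pathway targets went both ways, with medians of 0.01 (−0.06 to 0.08) and −0.12 (−0.24 to −0.06), and in females with 0.048 in the progenitor and 0.17 in the differentiating clusters. In males 3 of 15 were above 0.5 and 3 below −0.5, and in females 3 and 5. The hedgehog receptor gene Ptch1 had −0.47 in males and −0.98 in females, and the pathway target Gli1 had −0.75 and −1.26. In the same order Sfrp1 had 1.22 and 1.09, and Ccnd2 had 0.66 and 0.51. Igf2 was at 26.3 and 0.210 CPM in SG and YSG males and at 40.6 and 9.97 CPM in females. YAP and TAZ targets had medians of −0.25 (−0.30 to −0.20) in males and −0.25 (−0.36 to −0.18) in females, at percentiles 0.25 and 0.36. In the progenitor clusters they were −0.30 and −0.52, and in the differentiating clusters −0.027 and −0.17. Of 17 measured, 6 and 7 were below −0.5. Ccn1 had −1.50 in males, Tead1 0.00 and Foxf2 2.23.

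Lists tied to immune recognition had genotype medians near 0 in the granule lineage, apart from interferon response genes in females. MHC class I presentation genes had medians of −0.01 (−0.07 to 0.03) in males and 0.00 (−0.06 to 0.02) in females over 10 genes. H2-D1 had −0.02 and H2-K1 −0.49 in males. Interferon response genes had 0.12 (0.00 to 0.19) and 0.37 (0.26 to 0.46), with 6 of 47 measured. Irf9 had 0.18 and Cxcl10 0.31 in males. Chemokines and cytokines had 0.06 (−0.18 to 0.22) and 0.16 (0.09 to 0.22) over 7 genes, and −0.43 in females within the progenitor clusters. Csf1, a growth factor of macrophages, had −1.05 in males and Mif 0.22. Immune checkpoint ligands had −0.10 (−0.24 to 0.04) and −0.01 (−0.02 to 0.01) over 7 genes. The galectin gene Lgals1 had −1.20 in males, and Cd47, which encodes a signal against phagocytosis, was at 48.4 and 48.7 CPM in SG and YSG males and at 52.1 and 92.7 CPM in females. These genotype medians lay within the central 95% of random lists. Between YSG males and YSG females, chemokines and checkpoint ligands were lower in males, with medians of −0.35 (−0.43 to −0.28) and −0.27 (−0.35 to −0.20), and in SG the medians were −0.01 and −0.05. Without the clusters of 1 library, the checkpoint ligand median in YSG was 0.040.

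p53 and apoptosis genes had medians of 0.30 (0.24 to 0.34) and 0.23 (0.13 to 0.28), at percentiles 99.9 and 98.3, where Pmaip1 had 0.91, Mdm2 0.26 and Cdkn1a 0.01 in males. Hypoxia and glycolysis genes had 0.17 and −0.10, and immediate early and dissociation stress genes 0.25 and −0.06. The latter were at −0.034 in males without the clusters led by Hspa1a or Fos. Over all clusters, males had Hspa1b at 1.86, Hsp90aa1 at 0.75 and Jun at 0.03. Members of the homeostatic and disease-associated microglia lists were measured here in granule-lineage clusters, and the source of these transcripts was not tested. Their medians were 0.12 and −0.30 over 6 genes and 0.04 and 0.26 over 13. Fewer than 5 members of the lists for MHC class II presentation, complement and phagocytosis, alternative macrophage activation, T and NK cytotoxicity, T cell exhaustion and regulation, haemoglobin, Y-linked genes and X inactivation were measured, so they have no median.

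**Figure D3:**
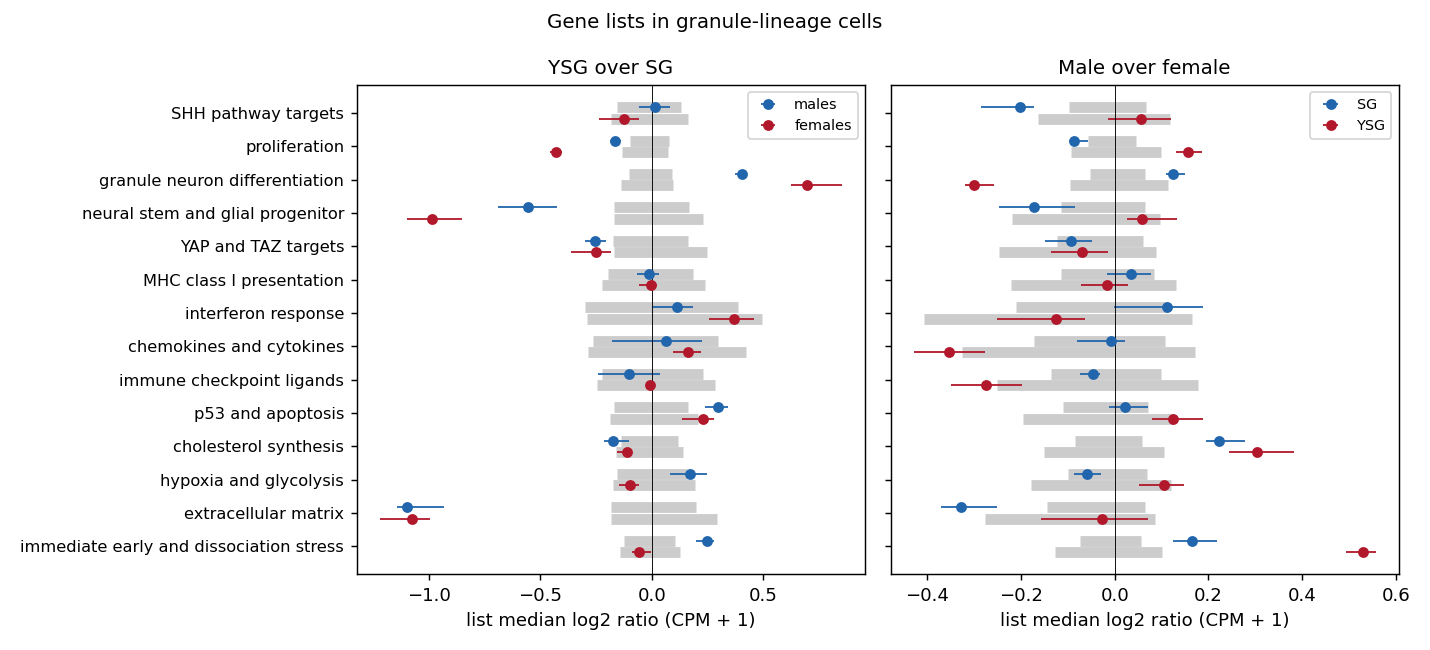
Points are list medians of the log2 ratio in granule-lineage cells (x axis) for each gene list (y axis), for YSG over SG on the left and male over female on the right. Bars are 95% counting intervals and grey bands the central 95% of matched random lists. Extracellular matrix genes lie lowest on the left, at −1.10 in males and −1.07 in females, and cholesterol synthesis genes lie at 0.22 and 0.30 on the right.

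Between the sexes, cholesterol synthesis genes had more transcripts in the male libraries of both genotypes. Their male over female medians were 0.22 (0.20 to 0.28) in SG and 0.30 (0.24 to 0.38) in YSG, each at percentile 100, with 3 and 4 of 18 above 0.5. By genotype they had −0.17 (−0.22 to −0.10) in males and −0.11 (−0.15 to −0.09) in females. Hmgcs1, an early enzyme of the pathway, was at 431 and 268 CPM in SG males and females and at 362 and 248 CPM in YSG. Insig1, a sterol-regulated gene, was at 161 and 94.9 CPM in SG and at 161 and 97.8 CPM in YSG. The other genes named as higher in males were Insm2, Fosb and Mxd1, with log2 ratios of 0.56, 0.56 and 0.54 in SG and of 0.79, 0.63 and 1.02 in YSG. Fosb is an immediate early gene, and that list was also higher in males, with medians of 0.16 (0.12 to 0.22) in SG and 0.53 (0.49 to 0.56) in YSG. Within the differentiating clusters alone the list median in SG was −0.021 and the ratio of Fosb in YSG −0.29. The genes named as higher in females were Runx1, Ifitm10, Lsp1, Trim47 and Col6a1, with male over female log2 ratios from −0.72 to −0.69 in SG and from −1.08 to −0.75 in YSG. X-inactivation escape genes were lower in males, with medians of −0.37 (−0.40 to −0.34) and −0.25 (−0.29 to −0.20), and their genotype medians were 0.06 in males and −0.15 in females. Across 10389 genes, the male over female ratios of SG and YSG had an r of 0.21 and a rho of 0.28. These leave out the Y-linked and X inactivation genes, among which Ddx3y and Xist went the same way in both genotypes. Of the other genes, 5 were beyond 2-fold in both genotypes, and 0 of these went the same way. With 1 library per sex and genotype, these differences cannot be separated from those between single libraries.

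Some genes had genotype ratios that went opposite ways in males and females. Mid1 was at 6.10, 38.3, 36.0 and 3.67 CPM in SG males, YSG males, SG females and YSG females. It lies at 169685199 to 170005736 near the end of the X chromosome, where the pseudoautosomal region begins. Ren1, the renin gene, was at 2.95, 0.267, 3.01 and 121 CPM. It lies on chromosome 1 at 133350510 to 133360325, on the plus strand. The homeobox genes Hoxb2 and Hoxb3 had 0 UMIs in YSG males, against 841 and 569 in SG males, so they were at least 235-fold and 159-fold lower. In YSG females they were at 29.3 and 25.8 CPM, against 13.4 and 6.91 CPM in SG females. Igfbp2 and Rcan2 went the same way as Ren1, with log2 ratios of −1.88 and −1.74 in males and 2.41 and 1.20 in females. Hist1h2ap and Hist1h2ae, histone genes with near-identical copies that short reads place poorly, had 2.45 and 0.49 in males and −2.04 and −0.90 in females. The heat shock gene Hsph1 had 1.25 and −0.10.

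In astroglia-like cells, genes of the interferon response, chemokines and MHC class I presentation were higher and cholesterol synthesis genes lower in YSG males than in SG males. The comparison rests on 90 and 159 cells, and YSG females had only 32, so gene lists were not compared in females. With the stricter filter the class held 43 and 122 cells in YSG and SG males, and at resolution 2.0 it held 21 and 70. The medians here are given for the main setting alone. The SG libraries also differed in these lists. Male over female medians in SG were −0.33 (−0.80 to 0.00) for interferon response, −0.32 (−0.55 to 0.02) for chemokines and −0.33 (−0.52 to −0.09) for MHC class I genes. For cholesterol synthesis genes the SG median was 0.22 (0.04 to 0.36). Shifts of this kind thus also occurred between libraries of 1 genotype, with smaller medians. Interferon response genes had a median of 1.10 (0.48 to 1.76), with 10 of 15 above 0.5, chemokines and cytokines 0.72 (0.32 to 1.55), with 8 of 14, and MHC class I genes 0.55 (0.00 to 0.85), with 8 of 14. Of the chemokines and cytokines 2 were below −0.5, among them Cxcl14 with 106 and 20 UMIs in SG and YSG males. Some of the members above 0.5 had intervals that reached below 0, such as Psmb10 at 0.75 (−0.28 to 1.81). Ifitm3 had 41 UMIs in SG males and 217 in YSG males, Cxcl10 had 18 and 252, Ccl2 had 7 and 106, and H2-K1 had 86 and 100. A few cells carried these counts, a clumping that the intervals leave out: Cxcl10 UMIs lay in 10 of the 90 cells, 102 of them in 1 cell, and Ccl2 UMIs in 4 cells. H2-K1 was found in a smaller share of the YSG cells, 15 of 90 against 44 of 159, with 36 of its 100 UMIs in 1 cell, and H2-D1 in 22 of 90 against 46 of 159. Cholesterol synthesis genes had a median of −0.72 (−0.97 to −0.47), with 12 of 18 below −0.5, among them Idi1 at −1.64 and Hmgcs1 at −0.93. Gfap, the intermediate filament gene of astrocytes, had 95 and 177 UMIs, and the water channel gene Aqp4 had 1197 and 300. The cells compared also differed in other glial markers: Olig1 had 189 and 9 UMIs, Hes5 137 and 6 and Sox2 142 and 15, and stem and glial progenitor genes had a median of −0.89 (−0.93 to −0.08). The granule list medians moved here as well, with −0.77 for proliferation and 0.60 for differentiation, and Barhl1, a granule gene, stood at 0.69 of its granule-lineage level over the glial clusters together.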

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

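The explanations below for Ren1 were tested on the libraries in which the pattern was seen; the test for free RNA was chosen after the result was seen. The test for handling replaced an earlier one inside clusters 10 and 19 of the SG libraries, where Hoxb2 and Hoxb3 had log2 ratios of 2.04 or more, because these genes lead the clusters. The differences between males and females, and between SG and YSG, were not tested, because each group is 1 library. Each result here was picked because values moved one way in 1 sex or genotype and the other way in the other, or because it lies outside the gene measurements of the comparisons.

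In list medians, male over female ratios in SG minus those in YSG came to −0.24 for proliferation, 0.42 for granule neuron differentiation, −0.23 for neural stem and glial progenitor genes and −0.16 for hypoxia and glycolysis. YSG over SG ratios in males minus those in females came to 0.42 for homeostatic microglia genes, 0.27 for hypoxia and glycolysis, 0.31 for immediate early and dissociation stress genes and 0.21 for X-inactivation escape genes. Other than for stem and glial progenitor genes, the 2 sides no longer went opposite ways under some settings. Within the differentiating clusters this held for proliferation (0.10 in SG), differentiation (−0.037 in SG) and hypoxia genes (−0.058 in YSG) in male over female ratios, and for homeostatic microglia (−0.065 in males), hypoxia (0.21 in females), immediate early (−0.13 in males) and X-inactivation escape genes (0.0048 in females) in genotype ratios. It held as well for proliferation (−0.21 in YSG) and immediate early genes (0.14 in females) within the progenitor clusters, and for hypoxia genes with no minimum (0.022 in females). Without clusters led by stress genes it held for homeostatic microglia (−0.013) and immediate early genes (−0.034) in males, and without clusters of 1 library for immediate early genes in females (0.027). For single genes the same difference between males and females was 5.46 for Mid1, 4.49 for Hist1h2ap, 1.39 for Hist1h2ae and 1.35 for Hsph1. It was −6.57 for Ren1, −5.10 for Hoxb3, −4.93 for Hoxb2, −4.29 for Igfbp2 and −2.94 for Rcan2. Among list members and genes fixed in advance it was 0.93 for Nes, 0.67 for Jun, 0.31 for Pkm, 0.27 for Calr, 0.24 for Smo, −0.74 for Socs1, −0.92 for Vcan and −1.18 for Cxcl14.

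The EYFP feature, which the labels do not mention, was counted in every library, at 34.8 CPM in SG males, 50.3 in YSG males, 42.5 in SG females and 28.2 in YSG females over all kept cells. Its YSG over SG log2 ratio in the granule lineage differed between males and females by 1.09.

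Ren1, Hoxb2, Hoxb3 and Igfbp2 were high in the YSG female library, where clusters 10 and 19 held 852 of 6343 granule-lineage cells and 81.8% of the Ren1 UMIs. Free RNA spread over that library would leave Ren1 at similar levels in the other granule-lineage cells, but these had 0.05 (0.0498) of the level in the clusters. Ren1 leads these clusters, so part of that gap can follow from the grouping. With clusters not used, Ren1 in YSG females was at 465 CPM in granule-lineage cells with a Hoxb2 or Hoxb3 UMI. In those without, it was at 28.8 CPM. A state made by the handling of that library alone would leave Ren1 and Igfbp2 unrelated to Hoxb2 and Hoxb3 in the SG libraries. There, cells with a Hoxb2 or Hoxb3 UMI had more Ren1 and Igfbp2 than the other granule-lineage cells, by log2 ratios of 1.27 or more, while Barhl1, a general granule gene, differed by 0.23 or less. This argues against handling as what links these genes, and does not cover their level: Ren1 in such cells was at 11.2 and 9.90 CPM in SG males and females and at 465 CPM in YSG females. Such cells were 11.8% of the granule-lineage cells in SG males, 12.7% in SG females and 14.9% in YSG females. These shares rest on single UMIs with no background share and are not compared, since clusters 10 and 19 held 0.45%, 0.79% and 13.4% of the granule-lineage cells in the same order, with 2.85%, 4.23% and 80.1% of the Hoxb2 UMIs. A population of Hoxb-expressing tumour cells in YSG females remains a hypothesis that was not tested further. Whether SG tumours hold the same population, and whether it goes with sex, with the animal or with the part of the tumour sampled is open.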

How the results depend on the processing

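The alternatives with the pan-leukocyte genes, the moved cluster, and the sums without clusters of 1 library or without clusters led by stress genes were chosen after the data were seen. Under all alternatives, list medians stayed within their counting interval 915 times, left it 203 times without a change of direction that the interval had excluded, and turned direction 30 times. Single-gene ratios did so 995 times, 194 times and 1 time. The leukocyte ratios kept their direction under the stricter filter, with doublets kept, at both other resolutions and with pan-leukocyte genes, from 0.87 to 1.20 in males and from 2.03 to 2.45 in females. In males the counting interval reached below 0 at resolution 2.0 (−0.040 to 1.83) and with the stricter filter (−0.014 to 2.53). With immune classes called per cell they were −0.85 and −0.23. Most of these calls were granule-lineage cells with 3 or more Vcan UMIs, which the rule calls by construction. The rule was not tried without Vcan. Libraries clustered alone gave no leukocyte cluster in males, so no ratio. With libraries clustered alone the male astroglia-like log2 ratio was −0.030 (−0.41 to 0.35), and with doublets kept −0.27 (−0.59 to 0.05). No paired analysis was possible because each group is 1 library. Unless stated, the cause of a change was not tested.

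The YSG minus SG difference in progenitor share, in percentage points, was −0.84 in males and −24.2 in females with the stricter filter, 0.92 and −23.9 with doublets kept, −8.12 and −30.4 at resolution 0.5, −16.1 and −30.2 at resolution 2.0, −9.61 and −12.8 with libraries clustered alone, −4.18 and −13.7 for thinned Mki67 or Top2a, and −0.39 and −26.3 with the cluster nearest the boundary moved. With libraries clustered alone the male minus female difference in SG was 5.01.

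Taking the differentiating clusters alone moved most lists. In males and females the genotype medians were then −0.37 and −0.13 for differentiation, 0.46 and 0.13 for proliferation, 0.17 and 0.17 for stem and glial progenitor genes, and −0.027 and −0.17 for YAP and TAZ targets. In males they were 0.046 for MHC class I, −0.023 for interferon response, −0.065 for homeostatic microglia and −0.13 for immediate early genes. In females they were 0.17 for SHH targets, 0.21 for hypoxia, 0.028 for extracellular matrix and 0.0048 for X-inactivation escape. Male over female medians there were, in SG, 0.10 for proliferation, −0.037 for differentiation, 0.0029 for checkpoint ligands and −0.021 for immediate early genes, and in YSG −0.058 for hypoxia and −0.29 for Fosb alone. In the progenitor clusters the genotype medians in males and females were 0.25 and 0.49 for proliferation, −0.30 and −0.52 for YAP and TAZ targets and −0.11 and −0.066 for MHC class I. In females they were 0.048 for SHH targets, 0.41 for differentiation, −0.43 for chemokines and 0.14 for immediate early genes. Male over female in YSG was −0.21 for proliferation and 0.082 for YAP and TAZ targets.

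With a pseudocount of 10 CPM, differentiation was 0.36 in males and 0.60 in females, and YAP and TAZ targets −0.18 in females. With equal weight per cell, differentiation was 0.34 in males and YAP and TAZ targets −0.37 in females. Thinned to 2000 UMIs, differentiation was 0.35 and MHC class I 0.044 in males, and YAP and TAZ targets −0.41 in females. MHC class I in females was −0.060 with DESeq2 size factors and 0.026 with no minimum, where hypoxia was 0.022. Without clusters led by stress genes, the male medians were 0.50 for differentiation, −0.013 for homeostatic microglia and −0.034 for immediate early genes. Without clusters of 1 library, immediate early genes were 0.027 in females and checkpoint ligands, male over female in YSG, 0.040. The number of cells limits the classes other than the granule lineage, where counts of 4 to 45 leukocytes or endothelial-like cells leave intervals several-fold wide.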

Other observations

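Of the tests below, those of the difference in cell states and of the inherited segment for Mndal and of the DNA flanking Yap1 were chosen before their results were seen, and the others after.

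Some SG cells held UMIs of the genes that mark clusters 10 and 19 of YSG females. In SG males 34 and in SG females 54 granule-lineage cells lay in these clusters, against 1 in YSG males. Cells with a Hoxb2 or Hoxb3 UMI numbered 889 in SG males and 875 in SG females, and their Meis2 level, a homeobox partner of Hox proteins, was 33.5 and 33.1 CPM against 9.60 and 10.0 CPM in the other granule-lineage cells. In YSG females there were 942 such cells, with Meis2 at 83.2 against 5.01 CPM. The genes that define these cells were picked after their levels per library were seen, and before the levels of Ren1 and Igfbp2 in these cells were computed.

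Near Mndal, Ifi203, which overlaps it in the annotation, was also scarce in SG, at 0.0963 and 0.0405 CPM in males and females, and present in YSG, at 3.17 and 11.04 CPM.

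Mndal was high in both YSG libraries and near 0 in both SG libraries. A different mix of progenitor and differentiating cells would not leave the ratio within each class, where the smallest log2 ratio was 5.43, and an interferon response would move the other interferon genes, whose higher median was 0.37. A general difference in cell states cannot be told apart, because the oligodendrocyte-like, precursor-like and astroglia-like clusters, in which the smaller ratio was 5.19, hold granule-lineage RNA, with Barhl1 at 0.69 of its level in the granule lineage, which the bound set before the result did not allow for. An inherited segment around Mndal that differs between the crosses may also account for it and cannot be told apart: of the 3 measured genes within 1 Mb that do not overlap it, 0 were beyond 2-fold in both sexes, but Ackr1 had 0.92 and 1.11 and Cadm3 0.75 and 0.74. Yap1 lies on chromosome 9 and Mndal on chromosome 1, so DNA linked to the floxed allele does not include Mndal.

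Leukocyte clusters took a larger share of the YSG libraries. More tissue from outside the tumour in the YSG samples would raise classes from outside the granule lineage. In females the highest astroglia-like or endothelial-like log2 ratio of shares under any setting of filter or clustering was −0.75 (−1.24 to −0.28), so these classes did not rise there. The unnamed cluster 18, led by the choroid plexus marker Ttr, held 35, 63, 24 and 162 cells in SG males, YSG males, SG females and YSG females. The source of these shallow cells was not tested, so more tissue of another kind cannot be told apart in females. In males more tissue cannot be told apart either, because the highest of these ratios was −0.030 (−0.41 to 0.35), with libraries clustered alone, against −0.72 (−1.11 to −0.34) with the libraries together. More blood cannot be told apart, because haemoglobin UMIs stood at 53.8 and 0.229 CPM in SG and YSG males and at 4.30 and 7.58 CPM in SG and YSG females, a difference of 3.27 CPM in females that goes against that in males. The filter on cell depth is open in males, where the ratio with 1000 UMIs and 500 genes was 1.20 (−0.01 to 2.53) on 9 and 19 cells. In females it was 2.45 on 6 and 30 cells, with an interval from 1.16 upward, against 2.41 with the usual filter, so the higher cut did not remove the difference there. With the stricter filter no neutrophil-like cluster was named, and all these cells lay in the microglia-like class. Cells under 500 UMIs are absent from the deposited matrices, so what a lower cut would add cannot be told. A difference that goes with genotype stays among the open explanations, as do age and the part of the tumour sampled, none of which the design separates.

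A hypothesis of passenger DNA was that strain DNA flanking the floxed Yap1 allele sets some of the genotype ratios. Over 32 genes within 10 Mb of Yap1 the median absolute log2 ratio was 0.14 in males and 0.17 in females, and the higher of its percentiles among matched random sets was 21.4. This argues against a larger change of these genes as a set. A change in a few of them would not move the median, so an effect on single genes is not excluded.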
